A study of Pseudomonas aeruginosa PAO1 with 12 samples.

How the data were processed

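Transcripts of Pseudomonas aeruginosa PAO1 were measured on 12 Affymetrix Pae_G1a arrays: 4 untreated, and 2 each with azithromycin at 8 µg/mL, azithromycin at 2 µg/mL, ceftazidime at 0.25 µg/mL and ciprofloxacin at 0.04 µg/mL. The deposited values are linear signal intensities per probe set, made by the authors with Affymetrix GCOS 1.4 per their processing notes and scaled array by array. The scaling target was not the same in every array. The mean between the 2nd and the 98th percentile was 500.2 to 500.3 in untreated 1 and 2 and in the treated arrays labelled 1, 2491 and 2494.8 in untreated 4 and 3, and 249.1 to 293.3 in the treated arrays labelled B. For the 4 untreated arrays an experiment information file was also there, which holds no measurement and was not used. It places these arrays on more than 1 day, and none was among the files for the treated arrays.

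Of 5896 probe sets, 14 Affymetrix controls were left out and 5882 tested. A PAO1 locus tag was in the identifier of 5545, of which 5504 were found in the RefSeq gene table (assembly ASM676v1), which gave the coordinates. Another 337 had no locus tag, among them 199 intergenic ones. Cross-hybridization to near-identical genes was not removed. The paired phenazine operons are such a case, and 10 of the 17 phenazine genes had a probe set of their own.

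The plan had been to take the log2 of the values as deposited. Since the arrays were on different scales, each was scaled to a trimmed mean of 500 instead. The linear values were quantile normalized between arrays with limma 3.58.1 in R 4.3.3 and then log2-transformed. Values as deposited were kept as an alternative. A linear model with 1 mean per labelled group and no replicate block was fitted with limma (lmFit, then eBayes with a mean-variance trend), which leaves 7 residual degrees of freedom and a median of 11.4 with the prior. Each treatment was compared with no antibiotic, azithromycin at 8 µg/mL with each of the other treatments, and ceftazidime with ciprofloxacin. A second model set all 8 treated arrays against the 4 untreated ones. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets tested within the comparison. Errors in the text are the standard deviation between arrays (SD) or, for a difference, the standard error (SE) from the model.

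There were 32 lists of genes, fixed with 639 genes, of which 631 had a probe set. Each was tested with limma's camera (inter-gene correlation preset at 0.01) and adjusted over the lists within the comparison, then with a correlation estimated per list and with fry. Counts of list members are given over all probe sets and adjusted over the list alone.

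Genes named in the text follow a rule. In a comparison with the untreated arrays these are the 12 largest increases and the 12 largest decreases that passed, had both treated arrays outside the untreated range, and were at or above the median intensity in the brighter group. In direct comparisons up to 6 each way were to be named, and where fewer than 3 genes passed, the 6 with the smallest p. Another 25 genes of quorum sensing, virulence, efflux, DNA damage and stress were named in advance for every comparison, as were up to 4 passing members of each list called. The comparisons, tests, lists, naming rule and most alternatives were set before the data were examined. Exceptions are named where they appear. Values in parentheses after a gene or list are log2 differences, and for a list the median over its genes.

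Alternatives were the values as deposited, median centring, an offset of 50 before the log, leaving out the dimmest 25% or 50% of probe sets, no mean-variance trend, a fold change of at least 2, the arrays of the 2 groups alone, leaving out each array in turn or all treated arrays of 1 letter, a replicate block, the mean of the 4 treatments in the 5-group model, and untreated arrays split in 2 sets of 2. Chosen after seeing the data were a common trimmed mean without quantile normalization, the scale of deposition as a block, only the 6 arrays at about 500, and leaving out untreated 3 and 4. Where leaving out an array leaves a treatment with 1 array, that array is assumed to vary like the other groups.

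The models were tested on simulated data with 5882 genes, 200 of them changed, at the number of arrays of the study. For azithromycin at 8 µg/mL against untreated, 4.4% of 2-fold, 45.2% of 4-fold, 82.4% of 8-fold and 91.2% of 16-fold changes were recovered, with a mean of 5.2 false calls. For all antibiotics against untreated the shares were 24.4%, 78%, 95.6% and 98.8%, with 7.4 false calls. A list shifted by 1 on the log2 scale was called in 20 of 20 simulations, with 1 other list called in all of them together. The genes were simulated as independent. These simulations therefore do not show how often camera with the preset correlation calls lists of correlated genes in error. Shared changes were compared with 100 simulations of unchanged groups set against the same untreated arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.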

Results

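Transcript levels of Pseudomonas aeruginosa PAO1 were measured on 12 Affymetrix Pae_G1a arrays. Cultures in ABT minimal medium with 0.5% casamino acids at 37 °C received an antibiotic at an OD600 of 0.3 in amounts that, per the study's description, left growth unaffected, and were harvested at an OD600 of 2.0. The antibiotics were the macrolide azithromycin at 8 or 2 µg/mL, the beta-lactam ceftazidime at 0.25 µg/mL and the fluoroquinolone ciprofloxacin at 0.04 µg/mL. Each of these 4 treatments had 2 arrays, labelled 1 and B, and 4 arrays came from untreated cultures. Median signal per array, as deposited, was 247, 284.8, 1034.7 and 1058.6 in untreated arrays 1 to 4, 197 to 239 in the treated arrays labelled 1 and 123.3 to 142 in those labelled B. The number of arrays limits the precision of every value below. The labels do not say whether arrays of 1 treatment came from separate cultures, so p-values measure the spread between these arrays only.

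The 12 arrays were on different scales, so they were brought to 1 distribution before any comparison. As deposited, the median gene was lower by 1.62 on the log2 scale with azithromycin at 8 µg/mL than without antibiotic. It was lower by 1.48 with azithromycin at 2 µg/mL, by 1.67 with ceftazidime and by 1.64 with ciprofloxacin. Quantile normalization left this shift between -0.03 and 0.02, and the changes below are relative to it. For the 92 list results that passed, the direction of the test, which is relative to the other genes, was the same as deposited, with median centring and with a common trimmed mean. These scalings differ from each other only by a constant per array, which moves all genes alike, so they are not separate checks. No detection call or background value was among the files. After normalization the median log2 intensity was 7.87 in every array, and 16 of the 28 named genes called higher against untreated lay below it in all 4 untreated arrays. The sizes of these increases depend on how dim signals are treated: an offset of 50 before the log made each of them smaller, and each kept its call. The named decreases were smaller with the offset as well.

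Treated arrays did not group by label. Each of the 8 treated arrays had its closest treated array, by Pearson's r across 5882 probe sets, under another label, so 0 of 8 matched their own. The array labelled azithromycin 2 µg/mL B was closest to the array labelled azithromycin 8 µg/mL B (r = 0.931), and its r with the other array of its own label was 0.812. The array labelled azithromycin 2 µg/mL 1 was closest to ceftazidime B (r = 0.921). Ceftazidime 1 was closest to ciprofloxacin B (r = 0.933), against 0.914 with ceftazidime B. These r are across genes, which are not independent replicates. All groups below are as labelled, and every direction given for an antibiotic holds only as far as these labels do.

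**Figure D1:**
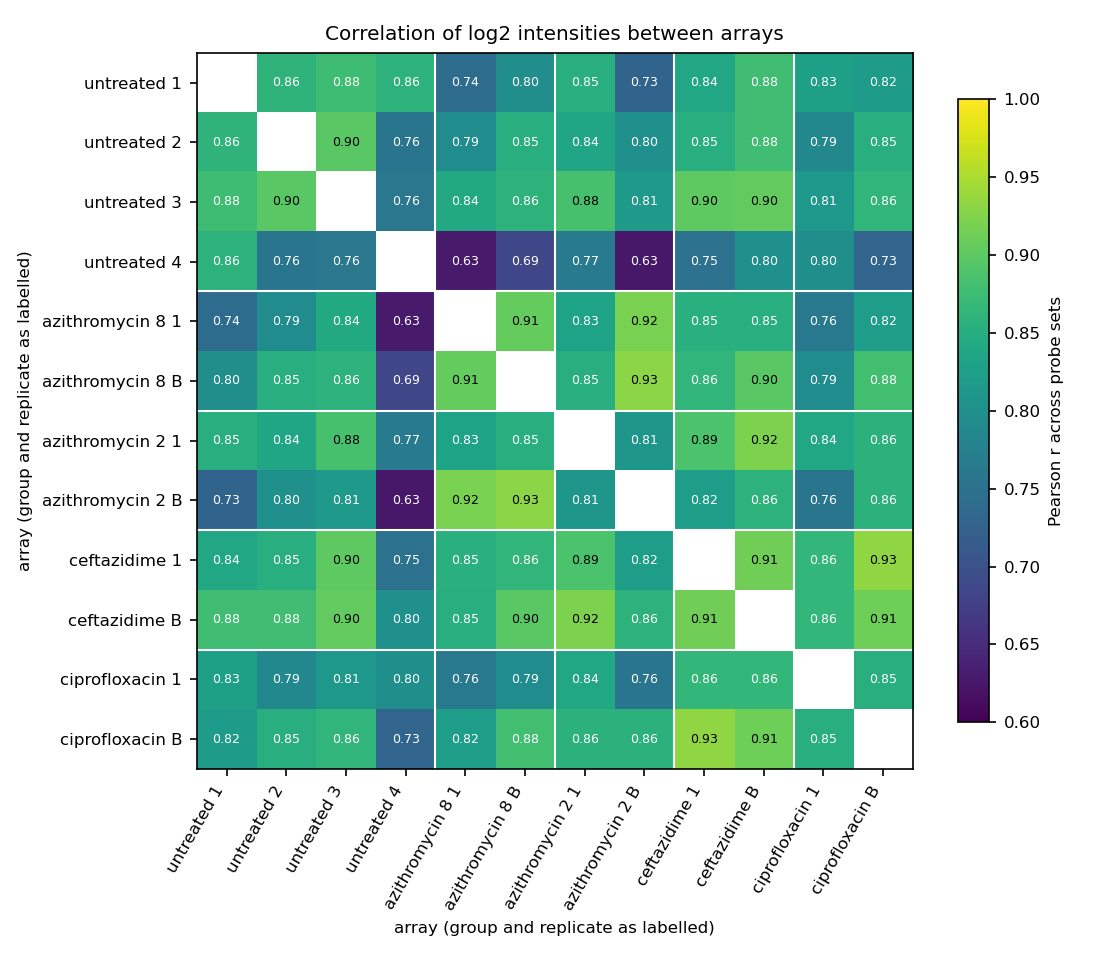
Pearson's r of log2 intensity across probe sets for each pair of the 12 arrays, in labelled order, with lines between groups. The highest value, 0.933, joins ceftazidime 1 and ciprofloxacin B.

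The first comparison asked which genes differed at the higher azithromycin dose. The genes ccoN2 and ccoO2, for subunits of a cbb3-type terminal oxidase, rose. For ccoN2 (PA1557, chromosome 1694852 to 1696279, RefSeq assembly ASM676v1) the log2 intensity was 10.73 ± 0.34 (SD, n = 2) against 6.70 ± 0.68 (SD, n = 4) untreated, an increase of 4.03 (SE 0.42, adjusted p = 0.00484 by limma). The denitrification genes nirS, nirM, nirC and norB also rose, with nirS (PA0519, 578394 to 580100) higher by 5.02 (SE 0.76, adjusted p = 0.0183). In the untreated arrays nirS was at 4.49 to 6.99, nirC at 1.83 to 5.63 and norB at 0.85 to 5.27, and with the offset the increases were 4.16, 3.42 and 2.57. Type III secretion, which injects toxins into host cells, rose through the effector gene exoS (PA3841, 4303141 to 4304502) by 2.16 (SE 0.33, adjusted p = 0.0183) and the needle-tip gene pcrV (PA1706) by 3.44 (SE 0.62, adjusted p = 0.03). The protease genes aprA and piv fell. The alkaline protease gene aprA (PA1249, 1355631 to 1357070) had 7.61 ± 0.51 (SD, n = 2) against 12.08 ± 0.81 (SD, n = 4), a change of -4.47 (SE 0.91, adjusted p = 0.0429), and the protease IV gene piv (PA4175, 4671319 to 4672707) changed by -3.78 (SE 0.61, adjusted p = 0.0214).

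In total 74 probe sets were higher and 29 lower at 8 µg/mL by limma, of 5882 tested. As deposited the same comparison gave 5 higher and 723 lower. With the scale of deposition as a block the count was 0 (727 at an unadjusted p under 0.05), as the median size of the 103 differences went from 2.82 (median SE 0.55) to 2.55 (SE 0.65), all with the same sign. Without untreated 3 and 4 together it was 15, and with only the arrays at about 500 it was 82, of which 31 were higher, 51 lower and 37 among the 103. Among the 12 largest increases were also PA3188 (5.40, or 2.95 with the offset), PA1673 (4.17), PA1701 (4.00), PA3190 (3.97), PA0802 (3.91) and PA4429 (3.79). The largest decreases included PA1914 (-4.68), PA4785 (-4.35, or -2.40 with the offset, where the call ended), the aminopeptidase gene PA2939 (-4.27), PA5059 (-3.92, or -2.38 with the offset) and the type VI secretion genes PA2372 (-3.58) and PA2370 (-3.47). The propionate gene prpB changed by -3.10 (adjusted p = 0.0483), with 11.77 in untreated 4 against 9.79 to 10.12 in the other untreated arrays. Of 25 genes named in advance, aprA and exoS passed. The nearest of the others were the sigma factor gene rpoS (-1.87, SE 0.47, adjusted p = 0.0658) and the quorum sensing regulator genes rhlR (-1.80, SE 0.47, adjusted p = 0.0697) and lasR (-2.10, SE 0.61, adjusted p = 0.0896). The elastase gene lasB differed by -2.77 (adjusted p = 0.115), and lasI by -0.12 (adjusted p = 0.918). Without the array labelled 1 the count was 0, and without B it was 2. It was 7 without untreated 1, 26 without untreated 2 and 63 without untreated 4. The calls of ccoN2, ccoO2, nirS, PA1673, PA3188 and PA3190 held without each untreated array. Those of the other named genes ended without untreated 1, among them exoS (2.16), piv (-3.61) and aprA (-4.21), which ended without untreated 2 (-4.74) and 4 (-4.25) too.

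Of the 40 type III secretion genes, 16 were called higher and 37 adjusted over the list alone. All 40 were positive, with a median log2 difference of 2.52 (camera adjusted p = 2.59e-25, adjusted p = 0.537 with an estimated correlation). The list mean was above the untreated mean by 2.41 in the array labelled 1 and by 2.68 in B. Denitrification and arginine fermentation genes had 4 of 33 called higher and 10 adjusted over the list alone, with a median of 1.33 (camera adjusted p = 3.1e-05, 0.537 with an estimated correlation). Where a list is called denitrification below, it is this whole list. A higher median of the list does not mean that arginine fermentation rose. With all antibiotics set against untreated, arcD, arcA, arcB and arcC differed by 0.11, 0.32, 0 and -0.67, and none was called. Of 18 genes for secreted enzymes and toxins, 4 were called lower and 10 adjusted over the list alone, with a median of -2.13 (adjusted p = 3.56e-06, 0.537 with an estimated correlation). In the list of 93 quorum sensing activated genes, 4 were called lower and 15 adjusted over the list alone, with a median of -0.91 (adjusted p = 6.37e-08, 0.537 with an estimated correlation). That call ended without the array labelled 1, where the median was -0.09, against -1.79 without B. The type VI secretion cluster HSI-III had 2 of 15 genes called lower and 12 adjusted over the list alone (median -2.48, or -1.42 without the array labelled 1, adjusted p = 7.89e-08, 0.537 with an estimated correlation). Ribosomal protein genes were positive in 54 of 54, with rpmG and rpmE called (median 1.36, adjusted p = 5.77e-14, 0.537 with an estimated correlation), while the list mean in each untreated array, against the other 3, ran from -1.65 to 0.95. Without untreated 4 the median was 0.87.

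Oxidative stress genes were the 1 list also called by fry, which asks whether a list moves on balance 1 way. Their median was -0.81 over 12 genes (camera adjusted p = 0.00326, adjusted p = 0.351 with an estimated correlation, fry adjusted p = 0.0213). The 10 measured phenazine genes had a median of -1.78 (adjusted p = 0.00567, 0.629 with an estimated correlation), which turned to 0.12 without the array labelled 1 and was -3.93 without B. The 3 rhamnolipid genes had a median of -3.09 (adjusted p = 0.0123, 0.537 with an estimated correlation), and that call too ended without the array labelled 1, at -1.80. Camera with the preset correlation also called peptidoglycan synthesis (0.48) and type IV pili (0.49) higher. It called R- and F-type pyocins (-1.01), the quorum sensing circuit (-0.83), pyoverdine (-0.55) and alginate (-0.47) lower. Without the array labelled B the quorum sensing circuit was at -0.55. Type IV pili lost the call without untreated 2 or the array labelled 1. Pyoverdine lost it without untreated 1, 2 or 3 or the array labelled 1, and alginate without untreated 1, 2 or 4 or the array labelled 1, while without untreated 3 it was at -0.81. The MexXY efflux genes, with a median of 1.27, did not pass (adjusted p = 0.125), nor did the quinolone signal genes (0.03, adjusted p = 0.702, mean -0.12) or the flagellum genes (-0.03, adjusted p = 0.594). Of the 32 lists 15 passed with the preset correlation and 0 with an estimated correlation.

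**Figure D2:**
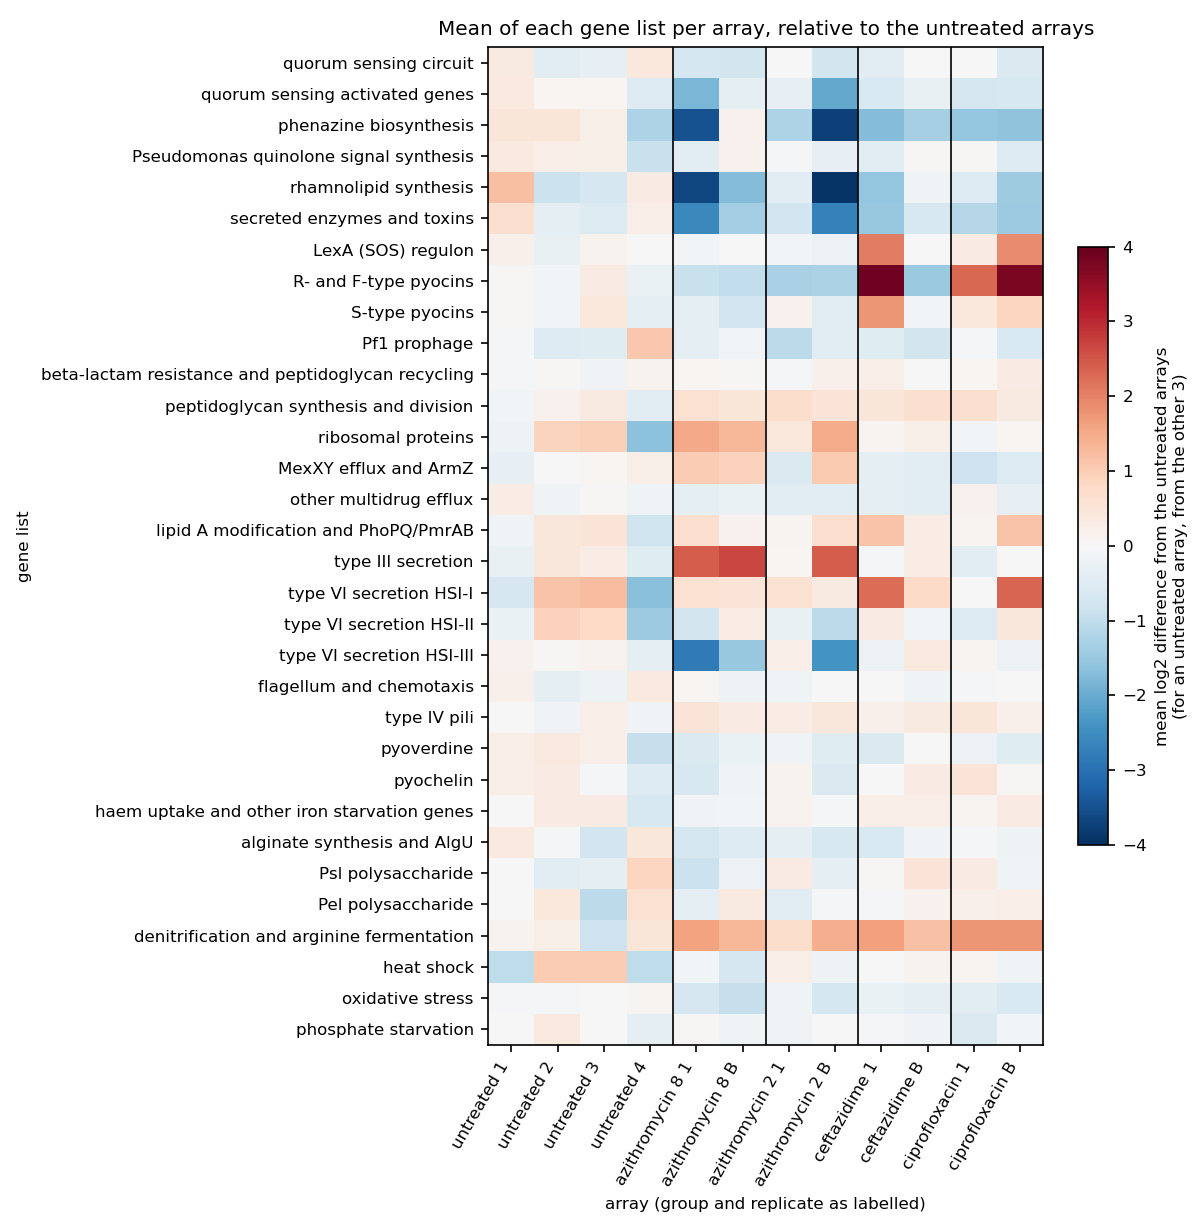
Mean log2 difference of each of the 32 gene lists (lines) from the untreated mean in each of the 12 arrays (columns, as labelled), where an untreated array is set against the other 3. Type III secretion is at 2.41, 2.68 and 2.43 in azithromycin 8 µg/mL 1 and B and azithromycin 2 µg/mL B, and at 0.09 in azithromycin 2 µg/mL 1.

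The next comparison asked the same of azithromycin at 2 µg/mL. Again ccoN2 and ccoO2 rose, ccoN2 to 10.59 ± 0.39 (SD, n = 2), an increase of 3.89 (SE 0.42, adjusted p = 0.00685 by limma), and ccoO2 by 4.33 (SE 0.58, adjusted p = 0.023). The third gene of this oxidase, ccoP2, rose by 2.74 (adjusted p = 0.0494), nirS by 4.44 (SE 0.76, adjusted p = 0.0494) and the outer membrane protein gene oprG (PA4067, 4544607 to 4545305) by 2.01 (SE 0.35, adjusted p = 0.0494). Also higher were PA3188 (4.60), PA3190 (3.59), PA1673 (3.33), PA1123 (3.28) and PA3281 (2.56), with PA3188 at 2.27 and PA3281 at 1.66 with the offset of 50. The protease gene piv changed by -3.50 (SE 0.61, adjusted p = 0.0494) and PA1877 by -2.97 (adjusted p = 0.0494), or -1.88 with the offset. These genes and the probe sets of 5S ribosomal RNA and of an isoleucine transfer RNA made up the 12 higher and 2 lower probe sets, against 2 higher and 297 lower as deposited. With the scale of deposition as a block the count was 0 (534 at an unadjusted p under 0.05), as the median SE of the 14 went from 0.53 to 0.68 with median sizes of 3.41 and 3.76. It was 0 too with only the arrays at about 500 or of the 2 groups, and 6 without untreated 3 and 4 together. No gene of the 25 named in advance passed. The smallest adjusted p among them was that of exoS (1.399, adjusted p = 0.135), and lasB differed by -2.53 (adjusted p = 0.249). Without the array labelled 1 the count was 173, and without B it was 1. It was 3, 5 and 2 without untreated 1, 2 and 3. Of the genes given here, ccoN2 kept its call without each untreated array, and the others lost it without at least 1 of them.

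At this dose type III secretion genes had a median of 1.35, with 0 of 40 called and 3 adjusted over the list alone (camera adjusted p = 4.72e-11, 0.434 with an estimated correlation). The call ended without the array labelled B, at 0.18. The list mean was 0.09 above the untreated mean in the array labelled 1 and 2.43 in B. Quorum sensing activated genes had a median of -1.03 (adjusted p = 2.53e-12, 0.434 with an estimated correlation). Their list mean was at -0.34 in array 1 and -2.04 in B, and the median was -2.05 without array 1 and -0.26 without B. Secreted enzymes and toxins had a median of -1.88, with 1 of 18 called lower and 8 adjusted over the list alone (adjusted p = 7.38e-07, 0.434 with an estimated correlation). Their list mean was at -0.75 in array 1 and -2.69 in B, and the median was -0.71 without B. Phenazine genes had a median of -2.45, with 7 of 10 lower adjusted over the list alone (adjusted p = 2.18e-06, 0.434 with an estimated correlation). Their list mean was at -1.25 in array 1 and -3.73 in B, and the median was -3.70 without array 1 and -1.37 without B. In untreated 4, against the other untreated arrays, the list mean was at -1.22, about that of array 1. Denitrification and arginine fermentation genes had a median of 1.22, with 10 of 33 higher adjusted over the list alone (camera adjusted p = 0.000729, 0.434 with an estimated correlation). The median was 0.65 without B and 0.71 and 0.73 without untreated 1 and 3. Ribosomal protein genes had a median of 0.89 (adjusted p = 4.51e-09, 0.694 with an estimated correlation), or 1.39 without array 1, 0.39 without B and 0.41 without untreated 4. The HSI-III list (-0.86, adjusted p = 0.00201, 0.711 with an estimated correlation) turned to 0.28 without the array labelled B. Without the array labelled 1 it was at -2.02, and type III secretion at 2.47. Also called were peptidoglycan synthesis (0.65), type IV pili (0.57), R- and F-type pyocins (-1.44), HSI-II (-0.63), rhamnolipid synthesis (-2.35), Pf1 prophage (-0.86) and other multidrug efflux (-0.47). Of these, rhamnolipid synthesis ended at -0.41 without the array labelled B, and Pf1 prophage at -0.33 without the array labelled 1 and -0.60 without untreated 4. HSI-II ended at -0.20 without the array labelled B, -0.42 without untreated 2 and -0.48 without untreated 3, and other efflux at -0.33 without the array labelled 1, -0.38 without untreated 1 and -0.52 without untreated 3. These calls held with other values without array 1, at -4.30 for rhamnolipid synthesis, -1.003 for HSI-II and 0.27 for peptidoglycan synthesis. Without untreated 4 they held at -1.02 for HSI-II, 0.415 for peptidoglycan synthesis and 0.37 for type IV pili. In all 14 of 32 lists passed with the preset correlation and 0 with an estimated correlation or by fry.

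With ceftazidime 6 genes were higher by limma and 0 lower, with 381 of 5882 at an unadjusted p under 0.05, against 0 higher and 91 lower as deposited. With the scale of deposition as a block the count was 0 (361 at an unadjusted p under 0.05), as the median SE of the 6 went from 0.45 to 0.60 with median sizes of 3.47 and 3.76. It was 0 with only the arrays of the 2 groups, 1 without untreated 3 and 4 together, and 37 with only the arrays at about 500, 1 of them among the 6. The 6 genes were ccoO2, which rose by 4.08 (SE 0.58, adjusted p = 0.0329), PA3190 by 3.71 (SE 0.49, adjusted p = 0.0245), ccoN2 by 3.38 (SE 0.42, adjusted p = 0.0245), PA1123 by 3.55 (adjusted p = 0.0481), PA3281 by 2.82 (1.88 with the offset, adjusted p = 0.0359) and oprG by 2.26 (SE 0.35, adjusted p = 0.0481). For oprG the log2 intensity was 12.33 ± 0.17 (SD, n = 2) against 10.07 ± 0.35 (SD, n = 4). The beta-lactamase gene ampC, which some beta-lactams induce, differed by 0.46 (SE 0.49, adjusted p = 0.892), and its list of beta-lactam resistance and peptidoglycan recycling genes had a median of 0.20 (adjusted p = 0.549). None of the 25 genes named in advance passed, and the smallest adjusted p among them was 0.559, that of the pyocin activator gene prtN (2.26, SE 0.71). The count was 0 without the array labelled 1 and 45 without B, and 0, 0 and 13 without untreated 1, 3 and 4. The calls of PA3281 and oprG also ended without untreated 2 (2.77 and 2.10).

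The arrays labelled ceftazidime differed from each other in DNA damage genes. For the recombinase gene recA (PA3617, 4051564 to 4052604) they gave 12.02 (array 1) and 10.07 (array B), against 9.95 ± 0.09 (SD, n = 4) untreated. For prtN (PA0610, 672777 to 673091) they gave 12.03 and 8.66, against 8.09 ± 0.45 (SD, n = 4). Ciprofloxacin 1 and B gave 10.63 and 12.07 for recA, and 11.12 and 11.91 for prtN. R- and F-type pyocin genes, phage-like killing particles under prtN, were positive in 39 of 39 with a median of 1.24 (camera adjusted p = 6.49e-07, 0.654 with an estimated correlation), yet -1.55 without the array labelled 1 and 3.95 without B. The LexA (SOS) list was positive in 15 of 15 with a median of 1.02 (camera adjusted p = 2.32e-05, 0.469 with an estimated correlation). It turned to -0.03 without the array labelled 1, where the call ended, against 2.11 without B. The list mean was at 2.04 and 0.01 in ceftazidime 1 and B, and at 0.32 and 1.90 in ciprofloxacin 1 and B. Ceftazidime 1 was thus level with ciprofloxacin B, its closest array, and the response is ceftazidime's only as far as the labels hold. Denitrification and arginine fermentation genes had a median of 1.19, with 6 of 33 higher adjusted over the list alone (camera adjusted p = 2.03e-10, 0.324 with an estimated correlation). Type VI secretion HSI-I genes were positive in 18 of 18 with a median of 1.42 (adjusted p = 2.19e-08, 0.469 with an estimated correlation). Their list mean was at 2.25 in array 1 and 0.75 in B, while each untreated array, against the other 3, ran from -1.68 to 1.22. The median was 0.77 without array 1, 2.20 without B and 0.92 without untreated 4. Peptidoglycan synthesis genes had a median of 0.66 (adjusted p = 6.49e-07, 0.324 with an estimated correlation), with 3 of 25 higher adjusted over the list alone. Secreted enzymes and toxins (-1.15), phenazine (-1.66) and quorum sensing activated genes (-0.29) were lower by camera (adjusted p = 6.77e-05, 8e-05 and 0.000659, and 0.469, 0.469 and 0.714 with an estimated correlation). Secreted enzymes and toxins were at -0.61 without array 1 and -0.74 without untreated 4, and quorum sensing activated genes at -0.53 without B. The phenazine list mean was at -1.73 and -1.31 in ceftazidime 1 and B, and at -1.22 in untreated 4 against the other 3. For quorum sensing activated genes these were -0.61, -0.28 and -0.52. The other calls were lipid A modification (0.59), type IV pili (0.39), S-type pyocins (1.25), Pf1 prophage (-0.81) and other efflux (-0.49). Lipid A modification ended at 0.28 and S-type pyocins at -0.32 without the array labelled 1. Type IV pili ended at 0.25 and Pf1 prophage at -0.78 without B, S-type pyocins at 1.38 without untreated 2 and Pf1 prophage at -0.32 without untreated 4. Other values with the call kept were 0.99 for lipid A modification and 1.98 for S-type pyocins without B, and 0.23 for type IV pili without untreated 4. In total 13 of 32 lists passed, and 0 did so with an estimated correlation or by fry.

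Ciprofloxacin was compared with no antibiotic in the same way. Here nirS rose by 5.19 (SE 0.76, adjusted p = 0.0244 by limma) to 11.22 ± 0.10 (SD, n = 2) from 6.03 ± 1.08 (SD, n = 4). The other genes called higher were ccoO2 by 4.06 (SE 0.58, adjusted p = 0.0239), PA3190 (3.62), PA1123 (3.55), ccoN2 by 3.53 (SE 0.42, adjusted p = 0.0182), PA1673 (3.45), PA3281 (2.99), PA3181 (2.74) and oprG by 2.15 (SE 0.35, adjusted p = 0.0395). The 1 gene called lower was PA2533 (-3.67, SE 0.53, adjusted p = 0.0239), named after its values were seen. That made 9 higher and 1 lower, against 2 higher and 145 lower as deposited. With the offset of 50 before the log 9 were higher and 0 lower, so the call of PA2533 ended. This gene was dim, at 3.755 in each ciprofloxacin array. With the scale of deposition as a block the count was 0 (598 at an unadjusted p under 0.05), as the median SE of the 10 went from 0.51 to 0.66 with median sizes of 3.54 and 3.71. It was 0 too with only the arrays at about 500 or of the 2 groups, and 1 without untreated 3 and 4 together. The DNA damage genes named in advance did not pass: prtN differed by 3.43 (SE 0.71, adjusted p = 0.0887), recA by 1.403 (SE 0.52, adjusted p = 0.305) and lexA (PA3007) by 1.75 (SE 0.76, adjusted p = 0.403). For lexA the arrays gave 9.48 (array 1) and 12.97 (array B), against 9.48 ± 0.06 (SD, n = 4) untreated. Without the array labelled 1 the count was 0, and without B it was 30. It was 0 without untreated 3 and 26 without untreated 4. The calls of PA1673, PA3181 and oprG also ended without untreated 1 (3.44, 2.73 and 2.19) and 2 (3.46, 2.56 and 2.00), and that of PA1123 without untreated 1 (3.76).

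R- and F-type pyocin genes were positive in 39 of 39 with ciprofloxacin, with a median of 3.10, 0 called and 34 higher adjusted over the list alone (camera adjusted p = 5e-24, 0.634 with an estimated correlation). The list mean was 2.31 above the untreated mean in array 1 and 3.76 in array B. The LexA (SOS) list was positive in 15 of 15 with a median of 1.403 (adjusted p = 7.34e-05, 0.705 with an estimated correlation), and ended at 0.16 without B. Denitrification and arginine fermentation genes had a median of 1.60, with 15 of 33 higher adjusted over the list alone (camera adjusted p = 1.1e-12, 0.26 with an estimated correlation). Secreted enzymes and toxins had a median of -1.06, with 3 of 18 lower adjusted over the list alone (adjusted p = 6e-05, 0.678 with an estimated correlation), and quorum sensing activated genes one of -0.33 (adjusted p = 9e-05, 0.741 with an estimated correlation). Without array 1 these were -1.84 and -0.58, and without untreated 4 the latter was -0.60. HSI-I genes, with a median of 1.04 (adjusted p = 0.000104, 0.736 with an estimated correlation), turned to -0.08 without B, and were at 2.22 without array 1 and 0.66 without untreated 4. Camera also called peptidoglycan synthesis (0.65), lipid A modification (0.67) and type IV pili (0.31) higher, and phenazine (-1.86), oxidative stress (-0.49) and pyoverdine (-0.33) lower. The pyoverdine list mean was at -0.23 and -0.48 in arrays 1 and B, and lower, at -0.92, in untreated 4 against the other untreated arrays. For phenazine these were -1.55, -1.61 and -1.22. Without B, lipid A modification ended at 0.005, phenazine at -1.77, oxidative stress at -0.43 and pyoverdine at -0.41. Type IV pili ended at 0.29 without array 1, and pyoverdine at -0.34, -0.21 and -0.21 without untreated 1, 2 and 3. Other values with the call kept were 1.06 for lipid A modification without array 1 and 0.39 without untreated 4, 0.51 for type IV pili without B, and -0.50 for pyoverdine without untreated 4. In total 12 of 32 lists passed, and 0 did so with an estimated correlation or by fry.

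**Figure D3:**
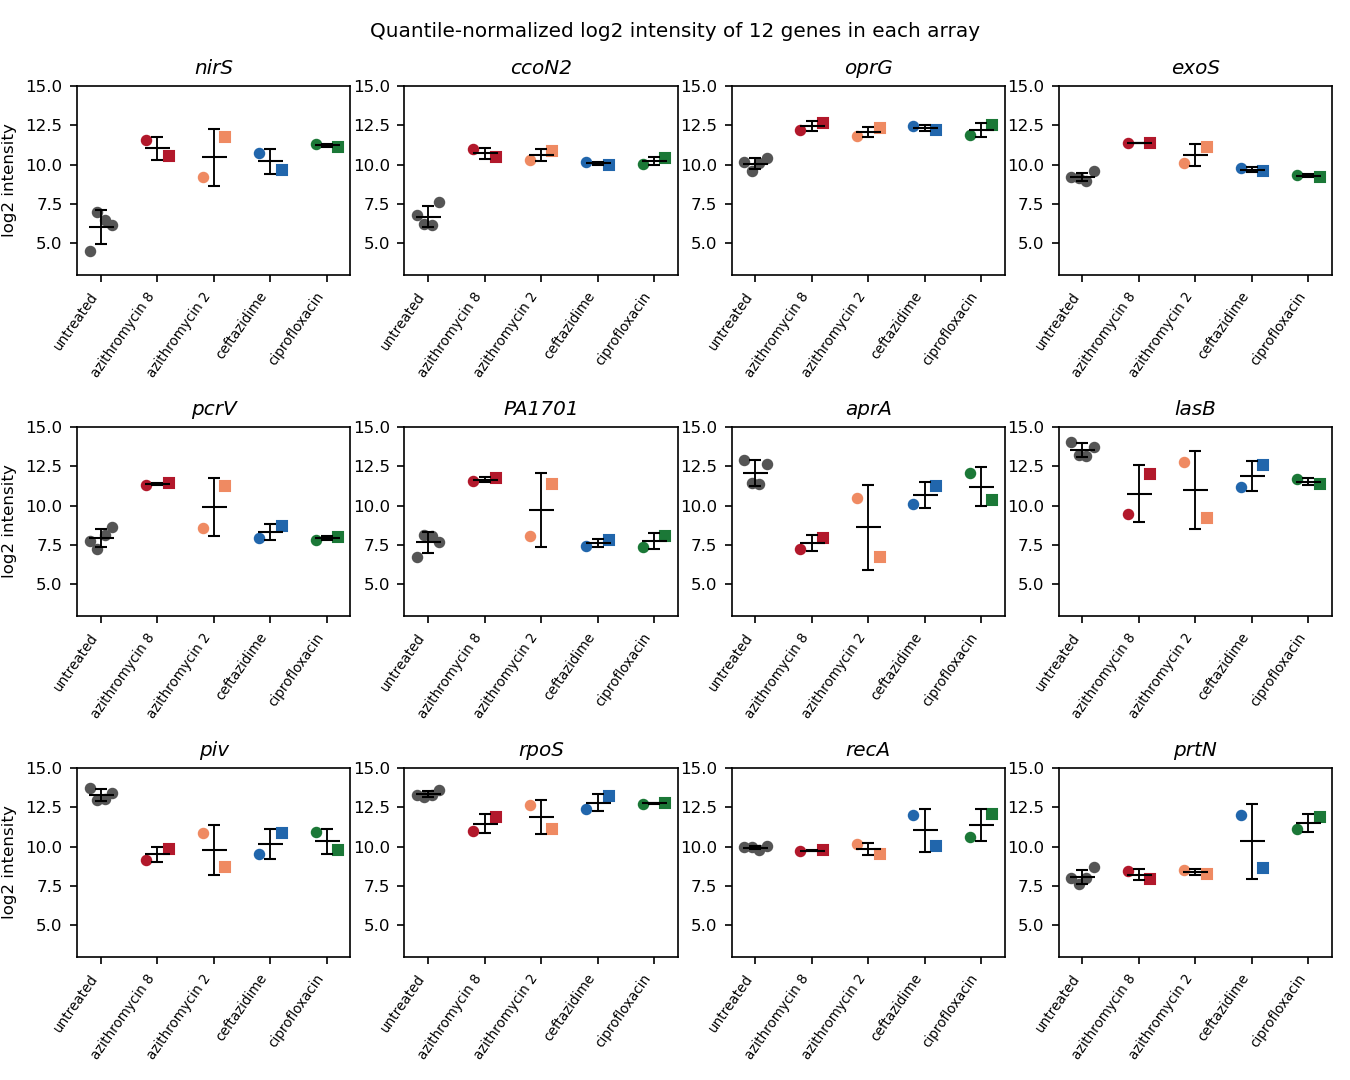
Quantile-normalized log2 intensity of 12 genes in each array by labelled group (circles, arrays with a number; squares, arrays labelled B), with bars at the group mean ± SD. For prtN the ceftazidime arrays sit at 12.03 and 8.66, and for ccoN2 all 8 treated arrays sit above all 4 untreated ones.

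All 8 treated arrays were then set against the 4 untreated ones, with differences between antibiotics left in the spread. The oxidase genes ccoN2 (3.71, SE 0.29, adjusted p = 2.21e-05 by limma) and ccoO2 (4.32, SE 0.39, adjusted p = 4.46e-05) rose, as did nirS (4.71, SE 0.52, adjusted p = 0.000304), nirC (5.19, SE 0.68, adjusted p = 0.000973) and nirM (3.23, adjusted p = 0.00643). With the offset of 50 nirS rose by 3.87 and nirC, at 1.83 to 5.63 in the untreated arrays, by 2.98. PA3190, the sugar-binding gene of a transporter, rose by 3.72 (SE 0.31, adjusted p = 2.96e-05), and PA2321 and PA2322, next to each other on the chromosome, by 3.08 and 3.23, with PA2322 at 1.99 with the offset. The dicarboxylate transporter gene dctA rose by 3.57 (adjusted p = 0.00511), with 2.88 in untreated 4 against 6.15 to 6.64 in the other untreated arrays. The protease gene piv changed by -3.33 (SE 0.41, adjusted p = 0.000692), PA2939 by -3.06 (adjusted p = 0.017), the chitinase gene chiC by -2.98 (SE 0.61, adjusted p = 0.0219) and the chitin-binding protein gene cbpD by -2.74 (adjusted p = 0.0215). Also among the largest decreases were prpB (-2.37), PA2031 (-2.35), PA1877 (-1.97) and PA0572 (-1.78). In all, 103 probe sets were higher and 54 lower, against 14 and 3694 as deposited. The count was 19 with the scale of deposition as a block, where the median SE of the 157 went from 0.36 to 0.51 with median sizes of 1.78 and 1.82. It was 1 with only the arrays at about 500, which alone carry the difference in the block fit, and 49 without untreated 3 and 4 together. Of the 25 genes named in advance, chiC passed, rhlR was next (-1.35, adjusted p = 0.0507) and lasB followed (-2.25, adjusted p = 0.0639). The count was 57, 83, 207 and 109 without untreated 1, 2, 3 and 4, 100 without azithromycin 8 µg/mL 1, 93 without azithromycin 2 µg/mL B and 255 without ciprofloxacin 1. Of the genes given here, 7 lost their call without untreated 1: PA2322 (3.10), PA2939 (-2.89), prpB (-2.58), chiC (-2.49), cbpD (-2.38), PA2031 (-2.105) and PA1877 (-1.745). Without untreated 2 prpB (-2.50) and PA2031 (-2.51) lost theirs. Without untreated 4 cbpD (-2.57), chiC (-2.565), PA2031 (-2.09), PA1877 (-1.97) and prpB (-1.91) did. Without the treated arrays labelled B the count was 17, and without those labelled 1 it was 53. In the first case ccoN2, ccoO2, nirS, PA3190 and piv kept their calls, and the other genes given here lost theirs, among them nirC (5.20, adjusted p = 0.0632), PA2321 (3.09, adjusted p = 0.0651), nirM (3.17, adjusted p = 0.0802), dctA (3.74, adjusted p = 0.107) and PA2322 (3.09, adjusted p = 0.244). In the second dctA, PA2322, chiC, cbpD, PA2031, PA1877 and PA0572 lost theirs.

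Called higher with each of the 4 treatments were 6 genes: ccoN2, ccoO2, oprG, PA1123, PA3190 and PA3281. No gene was called lower in all 4. The covariance of log2 fold changes across genes was 0.853 between the azithromycin doses and 0.45 to 0.511 between the other pairs, against 0.135 in 100 simulations of unchanged groups that share the same untreated arrays. Over the 6 pairs the mean excess was 0.401, and the mean covariance was 0.355 when each group was set against its own 2 untreated arrays. That covariance depended on which untreated arrays went where. It ran from -0.016 to 0.386 for azithromycin at 8 µg/mL with ciprofloxacin, and from 0.504 to 0.748 between the azithromycin doses. Genes are not independent replicates in these covariances.

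The azithromycin doses were also compared directly. No probe set differed by limma (0 of 5882, with 86 at an unadjusted p under 0.05 and a smallest adjusted p of 1). Among the genes nearest to a call were PA1897 (3.38, SE 0.80), PA4818 (2.61, SE 0.64) and iciA (2.53, SE 0.66), each with an adjusted p of 1. The gene pprA went the other way, with arrays at 3.46 and 4.89 at 8 µg/mL against 6.68 and 6.41 at 2 µg/mL. Type III secretion genes were higher at 8 µg/mL in 40 of 40, with a median of 1.24 (camera adjusted p = 3.82e-26, 0.622 with an estimated correlation), and the call ended at 0.14 without azithromycin 2 µg/mL 1. HSI-III (-1.12, adjusted p = 8.51e-08, 0.854 with an estimated correlation) turned to 0.08 without that array, and ribosomal protein genes (0.40, adjusted p = 8.89e-06, 0.873 with an estimated correlation) to -0.08. Without it MexXY efflux (0.66) turned to -0.01, Psl polysaccharide (-0.37) to 0.08 and denitrification (0.49) to -0.29, and the quorum sensing circuit (-0.42) kept a negative median of -0.07 while its test turned. Phenazine (0.81) turned to -0.95 without azithromycin 8 µg/mL B and -0.53 without azithromycin 2 µg/mL B, and HSI-II (0.53) to -0.12 without azithromycin 8 µg/mL B and -0.08 without azithromycin 2 µg/mL B. Without azithromycin 8 µg/mL 1, HSI-III was at -0.54, HSI-II at 0.93 and phenazine at 2.83. The quorum sensing circuit (-0.21), MexXY efflux (0.85), Psl (-0.20) and denitrification (0.14) lost their calls there, and the quorum sensing circuit also without azithromycin 8 µg/mL B (-0.26). Without azithromycin 2 µg/mL B, type III secretion was at 2.35, HSI-III at -2.94, MexXY efflux at 1.71, Psl at -1.10, ribosomal protein genes at 0.87, denitrification at 0.74 and the quorum sensing circuit at -0.70. Phenazine was at 1.95 without azithromycin 2 µg/mL 1, and Psl at -0.57 without azithromycin 8 µg/mL B. Heat shock (-0.48), oxidative stress (-0.44) and Pf1 prophage (0.37) made up the 12 of 32 lists called, and 0 were called with an estimated correlation or by fry. Without azithromycin 2 µg/mL 1, heat shock ended at -0.19 and oxidative stress at 0.02, where the test still pointed lower. Without azithromycin 8 µg/mL B they ended at -0.14 and -0.32, and heat shock ended at -0.61 without azithromycin 2 µg/mL B. Pf1 prophage ended without any 1 of the 4 arrays, at 0.17 to 0.54. The count of genes was 3 without azithromycin 2 µg/mL B.

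Azithromycin at 8 µg/mL and ceftazidime gave 0 differing probe sets by limma, with 496 at an unadjusted p under 0.05 and a smallest adjusted p of 0.456. The type III secretion genes popN (3.22, SE 0.60), PA1700 (3.48, SE 0.73) and PA1701 (4.01, SE 0.85) were among the nearest, with PA4574 (3.79), PA3619 (-3.57) and PA2372 (-3.87). Type III secretion genes were higher with azithromycin in 40 of 40 (median 2.35, 33 higher adjusted over the list alone, camera adjusted p = 9.08e-37, 0.379 with an estimated correlation). HSI-III genes were lower (-2.68, or -1.59 without azithromycin 8 µg/mL 1, 8 of 15 adjusted over the list alone, adjusted p = 1.03e-11, 0.379 with an estimated correlation). Ribosomal protein genes (1.18, adjusted p = 1.34e-16, 0.577 with an estimated correlation) and MexXY efflux genes (1.36, 5 of 5 positive, adjusted p = 0.00195, 0.379 with an estimated correlation) were higher. R- and F-type pyocins (-2.20, adjusted p = 9.11e-14, 0.577 with an estimated correlation) turned to 0.44 without ceftazidime 1, and the LexA (SOS) list (-1.16, adjusted p = 0.000198, 0.577 with an estimated correlation) ended at -0.25. Without ceftazidime B they were at -4.93 and -2.28. Quorum sensing activated genes (-0.72, adjusted p = 6.95e-05, 0.72 with an estimated correlation) had a median of -0.02 without azithromycin 8 µg/mL 1, where the test turned, and -1.43 without B. Of 32 lists 15 passed, and 0 did so with an estimated correlation or by fry. The count of genes was 44, all lower, without ceftazidime B.

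Between azithromycin at 8 µg/mL and ciprofloxacin the count was 0 by limma, with 810 at an unadjusted p under 0.05 and a smallest adjusted p of 0.161. The nearest genes were popN (3.46, SE 0.60), PA1006 (3.76), pcrH (3.41), PA2533 (3.44), exoS (2.10, SE 0.38) and PA1711 (2.77). Type III secretion genes had a median of 2.65, with 37 of 40 higher adjusted over the list alone (camera adjusted p = 7.04e-33, 0.615 with an estimated correlation). R- and F-type pyocins had a median of -4.12, with 38 of 39 lower adjusted over the list alone (adjusted p = 1.12e-27, 0.615 with an estimated correlation). HSI-III (-2.27, adjusted p = 9.78e-09, 0.615 with an estimated correlation) was lower, and MexXY efflux (1.95, adjusted p = 0.0022, 0.615 with an estimated correlation) and ribosomal protein genes (1.31, adjusted p = 2.75e-16, 0.665 with an estimated correlation) were higher. The LexA (SOS) list (-1.17, adjusted p = 0.000676, 0.665 with an estimated correlation) ended at -0.23 without ciprofloxacin B, and quorum sensing activated genes (-0.54, adjusted p = 0.0192, 0.945 with an estimated correlation) turned to 0.13 without azithromycin 8 µg/mL 1 and ended at -0.48 without ciprofloxacin B. Other values were -1.87 for the LexA (SOS) list and 1.19 for MexXY efflux without ciprofloxacin 1, -1.49 for HSI-III without azithromycin 8 µg/mL 1, and -1.28 for quorum sensing activated genes without azithromycin 8 µg/mL B. Of 32 lists 10 passed, and 0 did so with an estimated correlation or by fry.

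Ceftazidime and ciprofloxacin gave 0 differing probe sets by limma, with 116 at an unadjusted p under 0.05 and a smallest adjusted p of 1. PA1006 (2.96, SE 0.65), PA2533 (2.43, SE 0.61) and PA0683 (-3.45, SE 0.91) were among the nearest to a call. The 1 list called was R- and F-type pyocins, lower with ceftazidime (median -1.85, camera adjusted p = 9.89e-18, 0.984 with an estimated correlation, 38 of 39 negative). It turned to 0.85 without ceftazidime B, and was -4.52 without ceftazidime 1 and -1.20 without ciprofloxacin B. The count of genes was 34 without ceftazidime 1 and 1 without ciprofloxacin B, and lists called numbered 8 and 6 without ceftazidime 1 and B and 7 and 2 without ciprofloxacin 1 and B.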

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

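The tests of scale, spike-in, exchanged labels, replicate letter and untreated cultures handled apart were chosen after the result was seen, and that of chance was not. The test of quantile normalization uses a common trimmed mean and a division of the untreated arrays that were both taken up after the data were seen.

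Of 102 genes and lists examined in the 4 untreated arrays, 8 had an array far from the other 3, and chance alone gives about 1 in 20, or 5.1. Untreated 4 held 6 of them, on the log2 scale. The phenazine list was at 9.75 (others 10.85 to 11.03), the quinolone signal list at 10.41 (11.24 to 11.36) and the pyoverdine list at 10.94 (11.84 to 11.92). The gene prpB was at 11.77 (9.79 to 10.12), pqsA at 9.99 (11.51 to 11.81) and dctA at 2.88 (6.15 to 6.64). Untreated 1 had ampC at 6.38 (7.49 to 7.7), and untreated 2 had ftsL at 7.97 (8.66 to 8.73). Outside the genes compared, the Bacillus subtilis pheB control probe set stood at 16.2 times the array median in untreated 3 and 19.5 times in untreated 4, against 0.00825 to 0.144 times in the other 10 arrays, a difference that a spike-in added to those 2 arrays alone would give.

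The first pattern is that each treated array was closest to an array of another label. A batch shared by arrays of the same letter that outweighs the other differences between arrays is argued against. For it at least 6 of 8 arrays needed their closest array under the same letter, and 3 had it. A smaller batch of this kind cannot be excluded, since the closest array need not show it. Exchanged labels stay open. The labelled pairing ranked 40 of 105 possible pairings by mean r (0.871), yet the best (0.897) and the next (0.896) were too close to name any other pairing. A mean over all pairs cannot show whether only some of the labels were exchanged. In the brighter 50% of probe sets the labelled pairing ranked 29, at 0.804 against 0.881 for the best and 0.879 for the next. There too 0 of 8 treated arrays were closest to their own label. Azithromycin 8 µg/mL 1 had r = 0.965 with azithromycin 2 µg/mL B and 0.906 within its label. Azithromycin 2 µg/mL 1 had r = 0.963 with ceftazidime B and 0.716 within its label. Ceftazidime 1 had r = 0.969 with ciprofloxacin B and 0.818 within its label. Similar responses to different antibiotics, or cultures of 1 treatment that differed in state at harvest, could give the same picture and were not tested.

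The second pattern is the 157 probe sets that differed between treated and untreated arrays. Of the 495 possible splits of the arrays into 8 and 4, 100 were run, and 1 gave as many, the real one. The highest other count was 78, in the split with untreated 1 and 4, ceftazidime B and ciprofloxacin 1 set against the rest. This argues against chance only as far as the arrays are independent, which the labels do not say. The scale of deposition and the spike-in are argued against as the whole cause, because 81% of 100 genes picked on the B arrays against untreated 3 and 4 had the same sign among the 6 arrays at about 500, just past the bound of 80%, against 64% of all 5545 genes. With scale as a block the median size of the 157 differences went from 1.78 (median SE 0.36) to 1.82 (SE 0.51), all 157 with the same sign. The error widened and 16 stayed called. No scale but that of about 500 held both treated and untreated arrays, so this fit takes the difference from those 6 arrays alone. It is not separate from the fit on only those arrays, and the genes had been picked on these same arrays. Untreated cultures grown or hybridized apart from all treated ones cannot be told apart from the antibiotics, since 0 of 8 treated arrays have a label that gives a batch, so an effect of all 4 treatments remains a hypothesis.

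The third pattern is that untreated 1 and 4 differed from untreated 2 and 3, with heat shock genes at -1.002 and -1.011 against 1.009 and 1.004, each array set against the mean of the other 3, and ribosomal protein genes at -0.20 and -1.65 against 0.91 and 0.95. Untreated 3 and 4 shared scale and spike-in yet lay on opposite sides of this division, so these alone do not divide the arrays this way. The r between those 2 arrays was 0.759, lower by at least 0.1 than r of 0.897 (2 and 3) and 0.859 (1 and 4). This comparison was chosen with the division in view and partly restates it, so it is no separate test. Over all probe sets untreated 1 was as close to 2 (0.86) and 3 (0.875) as to 4, so it did not group with 4 there, and r was 0.756 between 2 and 4. Quantile normalization is argued against, as 89.7% of the ribosomal difference was there with a common trimmed mean (1.247 against 1.391). That difference is the mean of untreated 2 and 3 minus that of 1 and 4. The labels give no group that divides the untreated arrays this way, so no biological explanation was tested. The untreated arrays fell on more than 1 day, and the days were not set against this division. The calls against untreated rest on a group with this spread.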

How the results depend on the processing

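The common trimmed mean, the scale of deposition as a block, only the arrays at about 500, leaving out untreated 3 and 4, and list results under other scalings were chosen after the data were seen; the other alternatives were not. Unless a sentence says otherwise, the cause was not tested.

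Values as deposited gave 728 genes with azithromycin at 8 µg/mL against untreated (103 in the report), 299 with azithromycin at 2 µg/mL (14), 91 with ceftazidime (6), 147 with ciprofloxacin (10) and 3708 with all antibiotics (157). The construction shows why for these: untreated 3 and 4 are on a higher scale and the B arrays on a lower one. Values as deposited also gave 3 genes between azithromycin at 8 µg/mL and ciprofloxacin (0), 7 lists with ciprofloxacin (12) and 7 between ceftazidime and ciprofloxacin (1). They lowered the mean excess covariance to 0.191. They turned ftsL with azithromycin at 8 µg/mL to -0.204 and ampC with all antibiotics to -1.559. These turns go with the same shift of all genes, as the median gene lay at -1.62 and -1.6 in these comparisons. Median centring gave 3 genes with azithromycin at 2 µg/mL and 5 lists between its doses (12), and a common trimmed mean gave 5 genes with azithromycin at 2 µg/mL and 2 lists between ceftazidime and ciprofloxacin (1). An offset of 50 also gave 2 lists there. With the dimmest 50% left out, 7 lists differed between the azithromycin doses, and denitrification turned to -0.056 with fewer genes tested.

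Without a mean-variance trend the counts were 45 with azithromycin at 8 µg/mL, 7 at 2 µg/mL and 3 with ceftazidime. With only the arrays of the 2 groups, 0 genes were called with azithromycin at 2 µg/mL, ceftazidime or ciprofloxacin against untreated by limma (838, 381 and 671 at an unadjusted p under 0.05 with all arrays), 153 between azithromycin at 8 µg/mL and ceftazidime and 114 against ciprofloxacin, where 2 degrees of freedom were left, and 4 lists between ceftazidime and ciprofloxacin. The replicate labels gave no clear pairing of the arrays: r of the deviations between groups ran from -0.094 to 0.249. This check takes the treatment labels as right, so it cannot exclude a pairing. The replicate labels of the treated arrays also follow the scale of deposition. With a replicate block in direct comparisons, 0 genes were called in each of the 4, as without it, and 3 lists between ceftazidime and ciprofloxacin.

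With the scale of deposition as a block, limma called 0 genes for each of the 4 treatments against untreated and 19 for all antibiotics. Only arrays at about 500 gave 82 with azithromycin at 8 µg/mL, 31 higher and 51 lower against 74 and 29, with 37 among the 103. They gave 0 at 2 µg/mL, 37 with ceftazidime, 1 of them among the 6, 0 with ciprofloxacin and 1 for all antibiotics. Leaving out untreated 3 and 4 gave 15, 6, 1 and 1 for azithromycin at 8 and 2 µg/mL, ceftazidime and ciprofloxacin, and 49 for all antibiotics. For the 157 differences with all antibiotics the median SE was 0.36 with all arrays, 0.51 with the block and 0.48 with only arrays at about 500. The block fit and the fit on arrays at about 500 take this difference from the same 6 arrays, so they are not separate checks.

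Camera with an estimated correlation called 0 lists in all 8 comparisons. Fry called 1 with azithromycin at 8 µg/mL (oxidative stress) and 0 in the other 7.

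Leaving out 1 array, or all treated arrays of 1 letter, gave 0 to 105 genes with azithromycin at 8 µg/mL against untreated, 0 to 173 at 2 µg/mL, 0 to 45 with ceftazidime, 0 to 30 with ciprofloxacin and 17 to 255 with all antibiotics. Direct comparisons gave 0 to 3 between the azithromycin doses, 0 to 44 between azithromycin at 8 µg/mL and ceftazidime, 0 to 26 against ciprofloxacin and 0 to 34 between ceftazidime and ciprofloxacin. Lists called ranged from 9 to 20 with azithromycin at 8 µg/mL, 9 to 18 at 2 µg/mL, 6 to 14 with ciprofloxacin, 5 to 13 between the doses and 2 to 17 between ceftazidime and ciprofloxacin.

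List medians that turned when arrays were left out were, against untreated, phenazine with azithromycin at 8 µg/mL (-3.985 to 0.117), HSI-III at 2 µg/mL (-2.023 to 0.284), the LexA (SOS) list (-0.027 to 2.136), R- and F-type pyocins (-1.546 to 4.015) and S-type pyocins (-0.34 to 1.996) with ceftazidime, and HSI-I with ciprofloxacin (-0.081 to 2.217). Between the azithromycin doses they were the quorum sensing circuit (-0.703 to -0.021), phenazine (-2.422 to 4.035), ribosomal proteins (-0.142 to 0.918), MexXY (-0.184 to 1.707), HSI-II (-0.658 to 1.194), HSI-III (-3.88 to 0.501), Psl (-1.303 to 0.238), oxidative stress (-0.641 to 0.025) and denitrification (-0.29 to 0.752). For the quorum sensing circuit the direction of the test turned, not the sign of the median, and for LexA (SOS) and oxidative stress the sign, not the direction of the test. Against ceftazidime, quorum sensing activated genes with azithromycin at 8 µg/mL (-1.432 to -0.018, where the test turned) and R- and F-type pyocins (-5.04 to 0.499) did so, against ciprofloxacin quorum sensing activated genes (-1.418 to 0.146), and between ceftazidime and ciprofloxacin R- and F-type pyocins (-5.223 to 1.582).

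The call of ccoN2 with all antibiotics held under every alternative run. Signal over background is unknown, as no background value was among the files, and an offset of 50 made the named increases of the 16 genes dim in all 4 untreated arrays smaller.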

Other observations

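Both hypotheses here, with their gene lists and tests, were chosen after the called genes were seen.

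Genes higher with all antibiotics set together against no antibiotic included several of glucose and gluconate use, such as zwf (2.61, adjusted p = 0.0119 by limma), pgl (2.64, adjusted p = 0.0067), PA2321 (3.08) and PA3190 (3.72), beside oxidase and denitrification genes that bacteria use at low oxygen. Of 23 measured genes of glucose and gluconate use, 10 were called higher with all antibiotics against untreated and 1 lower, gcd (-1.71). A candidate explanation is higher use of these sugars in the treated cultures at harvest. The description of the medium given above names casamino acids and no sugar. The 12 genes not called had a mean of 8.08 ± 0.54 (SD, n = 8) against 6.92 ± 0.55 (SD, n = 4), a difference of 1.16. This value decides nothing, since the same difference on the same arrays set which genes were left out, gcd among them. The list was also written with the called genes in view and shares operons with them, so higher use of these sugars stays open.

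The second hypothesis was lower oxygen supply in the treated cultures, tested on genes of the Anr regulon, the regulator of growth at low oxygen. Of 21 measured, 6 were called higher. The other 15 were higher by 0.77 on average, 9.78 ± 0.63 (SD, n = 8) against 9.02 ± 0.82 (SD, n = 4). In 3 of the 8 treated arrays their mean was above all untreated arrays. Among these 15, 14 were positive, but the arginine fermentation genes arcD (0.11), arcA (0.32), arcB (0) and arcC (-0.67) showed little or no increase. The difference of the 15 genes decides nothing for the same reason, and lower oxygen stays open. In both cases untreated cultures handled apart from the treated ones would give the same values.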
